A study of Auxenochlorella pyrenoidosa with 8 samples.

How the data were processed

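Messenger RNA of a green alga, Auxenochlorella pyrenoidosa (also called Chlorella pyrenoidosa), strain FACHB-9, was sequenced from 8 samples taken at 4 times of CO2 deprivation. Per the labels, cells grew in light on 5% CO2 for 5 days and were then moved to plain air, and samples were taken at 0, 1, 4 and 24 h. The submitters' design text describes a pair of independent biological experiments handled in a single batch, so each time point has 2 libraries, numbered 1 and 2. RNA was extracted with TRIzol, cleaned on columns and turned into libraries with an Illumina TruSeq kit, per the labels' protocols. Whether the kit kept strand information is not given in the sources used here.

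The deposited table holds RPKM values, reads per kilobase of gene scaled to the reads of the library, in 1 column per library for 10283 genes, per the file headers. TopHat, a spliced-read aligner, and HTSeq, a read counter, are named in the submitters' processing notes. Their versions and settings, and the name of the assembly, are not given in the sources used here. The deposited gene models are AUGUSTUS predictions, per the file headers, and hold 10284 genes and 10451 transcripts on 1231 scaffolds, with 162 genes that have more than 1 transcript. The model file also carries a score for each prediction and start and end positions of each feature, as the authors deposited them, counted from 1. The median model had 7 coding exons, a coding length of 1038 bp and a span of 3045 bp, and 86.6% of the genes had both a start and a stop codon. Of neighbouring models, 11 pairs overlapped.

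The length behind the deposited RPKM was worked out from the values. When each value was multiplied by the gene's end minus its start, introns included, and by the library's own scale, 100% of the values of every library came out as whole reads within 0.01 reads. With the spliced length or the coding length of the same models, about 2% did (2.13% and 2.13% in the first 0 h library). The authors' RPKM values therefore refer to the full gene span, of which the spliced transcript was 43.6% in the median gene. This makes the RPKM of a gene with long introns low beside that of a compact gene. Ratios of the RPKM of a gene between libraries do not depend on the length used, but a lower RPKM brings a gene closer to the filter and shrinks its fold change once a pseudocount is added. The recovered reads summed to between 16706278 and 35463138 per library, and these sums were the totals used in the RPKM. Reads outside the listed genes therefore do not enter the values. A single read in a gene of 1 kb span stood for 0.0282 to 0.0599 RPKM.

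The files pair the gene numbers with no gene name or product, and no other annotation of this strain was used. Of 19 gene lists fixed by keyword, among them the carbon-concentrating mechanism, photorespiration, the Calvin cycle, light-harvesting antenna, ribosomal proteins, organelle-encoded genes and chaperones, 0 could be measured, so no gene set test and no list of RNA quality genes was run. Genes are therefore given by number and position. The rule for naming them took, for each comparison, up to 2 genes that rose and 2 that fell with the largest log2 fold change among called genes with a mean RPKM of at least 10 and no overlap between the groups compared.

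From the deposited values, log2(RPKM + 1) was computed, where the added 1 RPKM is the pseudocount. Fold changes from the fit are on this scale and understate the change of low genes. Genes with a mean of at least 1 RPKM over the 8 libraries were tested, which kept 9326 and left out 957. limma 3.58.1 in R 4.3.3 was fitted to all 8 libraries in 4 groups of 2, with an intensity trend and robust variance moderation, 4 residual degrees of freedom and a median of 3.63 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The contrasts were 1 h, 4 h and 24 h against 0 h, 4 h against 1 h and 24 h against 4 h, and an F test joined the 3 contrasts against 0 h. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

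Alternatives changed the pseudocount, the filter, the scaling between libraries, the variance moderation, the groups in the fit, the replicate number as a block, a fold threshold and each library in turn. The scaling alternatives were a trimmed mean of log ratios (trimming 30% of ratios and 5% of levels at each end), quantile normalization and rescaling to TPM. As a count-based test, limma's voom was run on the recovered reads, with totals scaled by the same trimmed mean. Leaving out both libraries numbered 1, or both numbered 2, at 1 h and 24 h, thinning the reads of every library to the smallest total, and giving each time its own 0 h library in the correlation of fold changes, were added after the data had been seen.

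Replicates were compared by correlation over all genes and by a chi-square test of the recovered reads over genes with at least 10 reads. No pair of libraries agreed within sampling noise, and each was counted as a sample of its own as labelled. The test covers counting error only, so it cannot exclude libraries prepared again from the same RNA. The chi-square per degree of freedom was lowest for the 4 h pair, at 20.2. The fit was tested on simulated reads drawn for the real genes with the real library sizes. Each gene had the spread estimated in the fit, the same in all groups. The real median SD on the log2 scale was 0.082 at 4 h and 0.2 at 0 h. The rates below may therefore differ from those of the real comparison. For 4 h against 0 h, with 9305 genes in the step, limma recovered 39% of 2-fold changes and 93.9% of 4-fold changes with 9 false calls. voom recovered 39% and 92.9% with 7 false calls. A permutation test of neighbouring genes by shuffled positions found no excess in a simulated random set (p = 0.85) and an excess in the same set with planted pairs (p = 0.0001, the smallest 10000 shuffles can give). Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.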

Results

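The series follows how the transcript levels of a unicellular green alga changed when its CO2 supply was cut. Such algae are known to answer a fall in CO2 by inducing a carbon-concentrating mechanism of bicarbonate transporters and carbonic anhydrases. Auxenochlorella pyrenoidosa FACHB-9 grown for 5 days on 5% CO2 was shifted to air, and RNA was sequenced at 0 h (n = 2), 1 h (n = 2), 4 h (n = 2) and 24 h (n = 2). No culture kept on 5% CO2 beyond 0 h is among the samples used here, so time in culture and handling are not separated from the change to air. Reads assigned to genes came to 16706278 and 23106515 at 0 h, 21375129 and 18314005 at 1 h, 18489074 and 35463138 at 4 h, and 18915889 and 19388209 at 24 h, for libraries 1 and 2 in turn. Between 75 and 125 of the 10283 genes had no read in a given library. The 10 most abundant genes took 5.07% and 5.32% of the reads at 0 h, 6.85% and 5.95% at 1 h, 7.89% and 7.37% at 4 h, and 6.56% and 8.13% at 24 h.

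Libraries of the same label were not always the closest to each other. The 4 h libraries correlated at r = 0.995 across genes and those at 0 h at 0.977. The library labelled 1 h number 2 correlated at 0.994 with the library labelled 24 h number 1, and at 0.967 with the other library labelled 1 h. The library labelled 1 h number 1 correlated at 0.985 with the library labelled 24 h number 2, whereas the 24 h libraries correlated at 0.951 with each other. The library closest to 1 h number 1 was 0 h number 2, at 0.986, so 0 h number 2, which serves as a reference in the comparisons with 0 h, was also closer to a library of another label than to its own replicate. These correlations are across genes, which are not independent replicates. The median SD between libraries of a group, on the log2 scale, was 0.2 at 0 h, 0.169 at 1 h, 0.082 at 4 h and 0.218 at 24 h (n = 2 each). Every comparison with a 1 h or 24 h group below rests on these labels as given. The fit also pools the spread over all 4 labelled groups. The SEs and calls at 4 h against 0 h therefore depend on the 1 h and 24 h labels too, while the fold changes there do not.

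**Figure D1:**
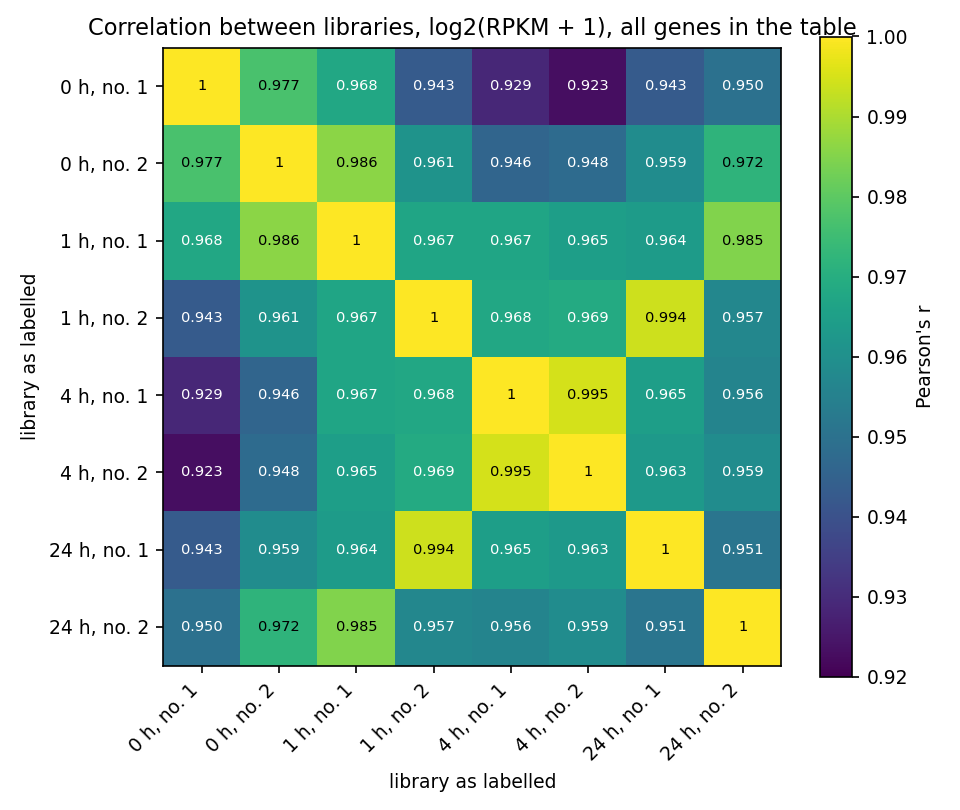
Pearson correlation of log2(RPKM + 1) over all 10283 genes between the 8 libraries, with rows and columns in the order of the labels and the color running from 0.92 to 1. The library labelled 1 h number 2 and that labelled 24 h number 1 stand at 0.994, above the 0.967 and 0.951 within the 1 h and 24 h labels.

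The comparison of 4 h with 0 h asked which genes had changed after 4 h in air, and it held nearly all the changes that passed the test. Of 9326 genes, 201 rose and 930 fell (limma, adjusted p under 0.05), so 82.2% of the 1131 called genes fell. By 4-fold or more, 54 genes rose and 67 fell, and by 2-fold or more 142 rose and 540 fell. Of 4 bins of equal size by mean level, the lowest (median 3.1 RPKM) held 18 genes that rose and 247 that fell. The highest (median 68.9 RPKM) held 89 that rose and 186 that fell.

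The largest rise belonged to g4952, a gene of 6 exons and 834 bp coding length on the minus strand of scaffold00661 (19537 to 21470). It went from 1.14 ± 0.0727 RPKM at 0 h to 397 ± 33.0 RPKM at 4 h (SD, n = 2 each), 350-fold in the means, with a log2 fold change of 7.54 (SE 1.76, limma adjusted p = 0.046). Its 0 h level rested on 35 and 53 reads. Next was g4050, with 5 exons and 744 bp coding length on the minus strand of scaffold00514 (2025313 to 2029337), which went from 4.36 ± 0.483 to 872 ± 74.6 RPKM, a log2 fold change of 7.35 (SE 1.53, limma adjusted p = 0.035). The largest fall was that of g2865, a gene of 2 exons and 684 bp coding length on the plus strand of scaffold00366 (493722 to 494786). It went from 355 ± 388 to 6.94 ± 0.327 RPKM, a log2 fold change of -4.84 (SE 0.96, limma adjusted p = 0.032), and its 0 h libraries differed widely, at 80.6 and 629 RPKM. g897, with 19 exons and 2145 bp coding length on the minus strand of scaffold00066 (628977 to 636580), went from 109 ± 112 to 2.50 ± 0.0407 RPKM, a log2 fold change of -4.45 (SE 0.83, limma adjusted p = 0.027). Its 0 h libraries stood at 29.9 and 188 RPKM. The name of the assembly to which these scaffolds belong is not given in the sources used here.

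The calls of these 4 genes were close to the threshold, whereas the smallest adjusted p at 4 h over all tested genes was 0.000693 in limma. With the 0 h and 4 h libraries alone in the fit, g4952 and g4050 each had an adjusted p of 4.4e-05, and g2865 and g897 of 0.021 and 0.020. Under voom on recovered reads the adjusted p was 0.13 for g4952, 0.057 for g4050, 0.061 for g2865 and 0.037 for g897. g4952 also lost its call under trimmed-mean scaling and quantile normalization. With either 4 h library left out none of the 4 was called, and with either 0 h library left out g4952 and g4050 were not, while the log2 fold changes of the rising pair stayed between 7.26 and 7.62 in these leave-outs. The falling pair depended on the 0 h library: without library 1 g2865 stood at -6.31 and g897 at -5.75, and without library 2 they stood at -3.36 and -3.14, called in each case. The adjusted p over all alternatives reached at most 0.263, 0.227, 0.222 and 0.198 for g4952, g4050, g2865 and g897.

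**Figure D2:**
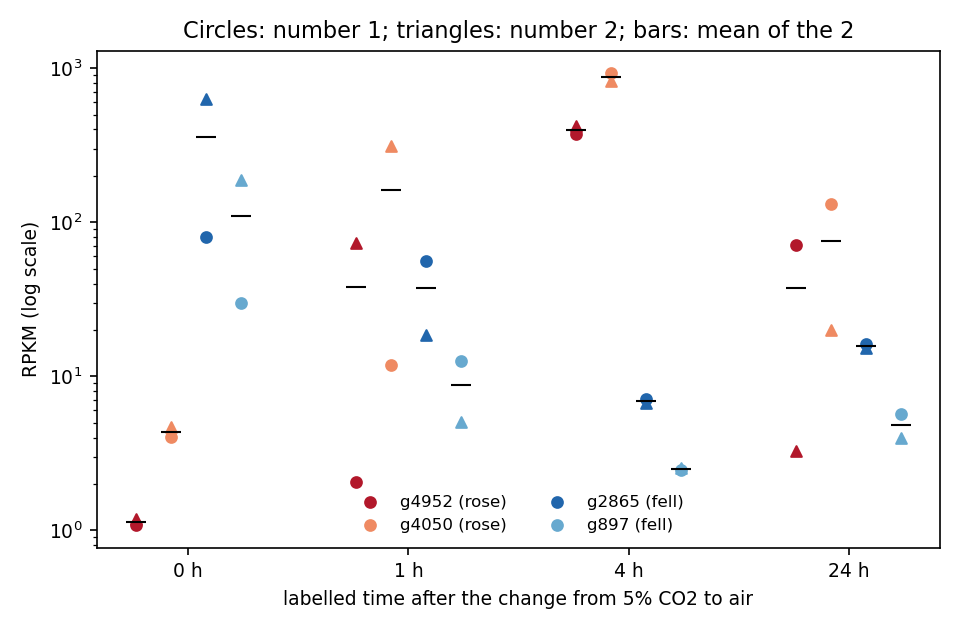
RPKM on a log axis of the 4 genes named for 4 h against 0 h, by labelled time after the change from 5% CO2 to air, with circles for library 1, triangles for library 2 and bars for the mean of the 2. g4952 and g4050 stand at 397 and 872 RPKM at 4 h, and at 1 h and 24 h their libraries lie far apart.

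The median gene was lower at 4 h than at 0 h by 0.20 on the log2 scale of the deposited RPKM (-0.20), and scaling by a trimmed mean of ratios brought this median to 0. The smallest called change was 0.58 in size, so each called gene lay beyond that shift, and relative to it g4952 and g4050 stood at 7.74 and 7.54 and g2865 and g897 at -4.64 and -4.25. The balance of calls moved with the scaling. After trimmed-mean scaling 298 genes rose and 404 fell (57.5% fell), after quantile normalization 255 rose and 359 fell (58.5% fell), and voom called 286 that rose and 411 that fell. With the 0 h and 4 h libraries alone in the fit, 410 rose and 1473 fell (78.2% fell), and 1112 of these genes were shared with the fit of all libraries. The number of called genes also depended on single libraries. It fell when 0 h library 1 or either 4 h library was left out, and it rose when 0 h library 2 was left out. In these fits the lone library left in a group was assumed to vary like the others.

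**Figure D3:**
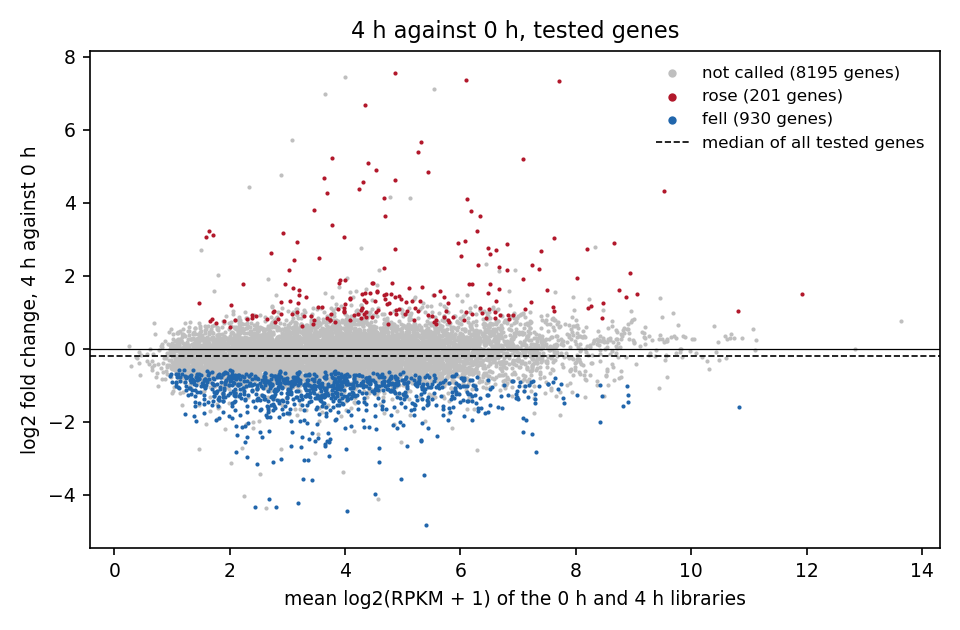
log2 fold change at 4 h against 0 h over the mean log2(RPKM + 1) of the 0 h and 4 h libraries, for 9326 tested genes, with genes that rose in red, genes that fell in blue and the median of all genes as a dashed line at -0.20. The 201 genes that rose reach a log2 fold change of 7.54 and the 930 that fell reach -4.84.

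At 1 h against 0 h, which asked for the early response, 0 of 9326 genes passed the test in limma, with a smallest adjusted p of 0.114, and voom called 0 as well. At an unadjusted p under 0.05 there were 953 genes in limma and 832 in voom, where 466 are expected by chance. Both fits pool the spread over all 4 groups, including the tight 4 h pair, so this chance value is approximate. With only the 0 h and 1 h libraries in the fit, which leaves fewer libraries to estimate the spread, limma gave 669 such genes. Relative to the 0 h mean, which also enters the call at 4 h, the 201 that rose at 4 h stood at a median log2 of 0.37 and 0.63 in the 1 h libraries, and the 930 that fell stood at -0.45 and -0.53, where the median of all tested genes was -0.09 and -0.08. For g4050 the libraries labelled 1 h held 11.9 and 312 RPKM, and for g4952 they held 2.06 and 73.8 RPKM. With 1 library left at both 1 h and 24 h, the spread would come from the 0 h and 4 h pairs alone, and the 4 h pair was the tightest. Calls in such leave-outs are therefore not read as changes at 1 h.

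At 24 h against 0 h, the late time point, limma again called 0 of 9326 genes, with a smallest adjusted p of 0.111, and voom called 0. At an unadjusted p under 0.05 there were 1716 genes in limma and 1381 in voom, against 466 expected by chance, with the same pooled spread. With only the 0 h and 24 h libraries in the fit, limma gave 880 such genes. The median of all genes stood at -0.16 on the log2 scale. The genes that rose at 4 h stood at a median of 0.55 and 0.52 in the 24 h libraries and those that fell at -0.59 and -0.57. g4050 was at 132 and 20.0 RPKM and g4952 at 71.1 and 3.28 RPKM in the libraries labelled 24 h. A leave-out of a library labelled 1 h or 24 h takes that group out of the estimate of the spread. Calls in such leave-outs are therefore not read as changes at 24 h either.

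**Figure D4:**
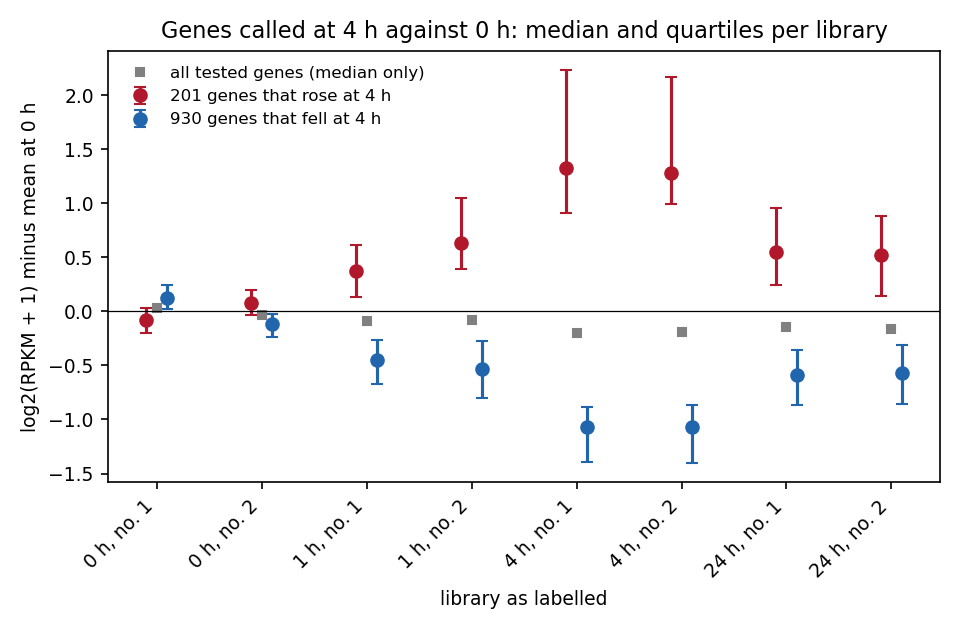
log2(RPKM + 1) minus the mean at 0 h in each of the 8 libraries, as the median (points) and quartiles (bars) of the 201 genes that rose at 4 h (red) and the 930 that fell (blue), with the median of all tested genes as squares. Medians of the red genes are 1.33 and 1.28 at 4 h and between 0.37 and 0.63 in the libraries labelled 1 h and 24 h.

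Levels at 1 h and 24 h lay between those at 0 h and 4 h for most genes called at 4 h. All 4 libraries of 1 h and 24 h lay between the 0 h and 4 h means for 133 of the 201 genes that rose (66.2%) and 731 of the 930 that fell (78.6%). Among the 8195 genes not called at 4 h this held for 877 (10.7%). Genes picked for a large difference between 0 h and 4 h leave more room between these means, so the shares are not on equal terms.

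Between 1 h and 4 h, 16 genes rose and 22 fell. The gene with the largest rise was g5138, with 12 exons and 1167 bp coding length on the plus strand of scaffold00704 (508519 to 513223), which went from 8.40 ± 5.49 to 82.5 ± 6.13 RPKM (SD, n = 2 each), a log2 fold change of 3.29 (SE 0.38, limma adjusted p = 0.021). g9605, with 11 exons and 3330 bp coding length on the minus strand of scaffold01246 (447308 to 454601), went from 5.94 ± 4.14 to 40.4 ± 1.39 RPKM (log2 2.72, SE 0.38, limma adjusted p = 0.042). The largest falls were those of g6836, with 15 exons and 1890 bp coding length on the minus strand of scaffold00992 (802838 to 807911), from 13.4 ± 3.5 to 1.77 ± 0.0091 RPKM, and of g7333, with 7 exons and 582 bp coding length on the minus strand of scaffold01012 (212099 to 213842), from 11.8 ± 1.78 to 2.34 ± 0.282 RPKM. Their log2 fold changes were -2.35 (SE 0.31) and -1.93 (SE 0.25), each with a limma adjusted p of 0.033. The 38 calls fell to 0 when only the 1 h and 4 h libraries were fitted and when either 0 h library, either 4 h library or 1 h library 1 was left out, and voom called 13 that rose and 10 that fell. There were 17 calls without 1 h library 2 and 106 without either library labelled 24 h.

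From 4 h to 24 h, 30 genes rose and 35 fell, and the named genes were those of the comparison of 4 h with 1 h, with the direction turned. g5138 went from 82.5 ± 6.13 to 6.46 ± 1.16 RPKM (log2 -3.49, SE 0.38, limma adjusted p = 0.026), beside 1.24 ± 0.328 RPKM at 0 h. g9605 went from 40.4 ± 1.39 to 4.01 ± 0.961 RPKM (log2 -3.06, SE 0.38, limma adjusted p = 0.034), beside 1.96 ± 0.0849 at 0 h. g6836 rose from 1.77 ± 0.0091 to 11.8 ± 4.45 RPKM (log2 2.16, SE 0.31, limma adjusted p = 0.046) and g7333 from 2.34 ± 0.282 to 12.9 ± 4.63 RPKM (log2 2.02, SE 0.25, limma adjusted p = 0.033). At 0 h these last genes had 32.9 ± 9.23 and 20.1 ± 0.312 RPKM. The 65 calls fell to 0 when only the 4 h and 24 h libraries were fitted and when either 0 h or either 4 h library was left out, with 1 call without 24 h library 2. There were 36 calls without either library labelled 1 h and 41 without 24 h library 1, and voom called 12 that rose and 21 that fell.

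The F test over 1 h, 4 h and 24 h against 0 h called 170 genes. The largest change was at 4 h for 168 of them (98.8%, 95% exact Clopper-Pearson interval 95.8 to 99.9 over genes, which are not independent), of which 52 rose and 116 fell. The other 2 fell most at 24 h, and none changed most at 1 h. In the leave-outs that follow, a group left with 1 library added nothing to the estimate of the spread. Leaving out any single library of 0 h or 4 h gave 0 calls, leaving out a library labelled 1 h gave 115 or 112, and leaving out a library labelled 24 h gave 286 or 268. With both libraries numbered 1 left out at 1 h and 24 h, 911 genes were called and 63.1% changed most at 4 h, and with both numbered 2 left out the values were 759 and 66.8%.

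No gene was called at more than 1 of the time points against 0 h, and none would be expected by chance since 0 were called at 1 h and at 24 h. Across the tested genes, log2 fold changes at 1 h and 4 h correlated at r = 0.78 (rho = 0.74), those at 4 h and 24 h at r = 0.74 (rho = 0.71), and those at 1 h and 24 h at r = 0.91 (rho = 0.89). All 3 share the 0 h libraries, and 100 simulations of unchanged groups with a shared 0 h group gave r = 0.50, at most 0.54, 0.54 and 0.56. The simulations gave a gene the same spread in every group. The real median SD was 0.2 at 0 h, 0.169 at 1 h, 0.082 at 4 h and 0.218 at 24 h. A tighter 4 h group raises the r of unchanged groups, so the simulated r is too low a mark for the pairs with 4 h. The covariances were 0.235, 0.246 and 0.181, against 0.046 simulated with that equal spread, which leaves differences of 0.189, 0.200 and 0.135. With a different 0 h library for each time, tried both ways after the data had been seen, r was 0.52 and 0.56 for 1 h with 4 h, 0.55 and 0.51 for 4 h with 24 h, and 0.56 both ways for 1 h with 24 h. The covariances were then 0.194 and 0.177, 0.190 and 0.203, and 0.134 and 0.130. For 1 h and 24 h as labelled, r was 0.42 with library 1 left out at both times and 0.44 with library 2 left out at both. For unchanged groups of that size, 100 simulations with the same equal spread gave 0.33 and at most 0.39. The covariances in these settings were 0.135 and 0.102, against 0.046 simulated, and r was 0.63 without 24 h library 1 alone.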

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

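The splits of the 1 h and 24 h libraries, the thinning of reads, the reading of the deviations by library number and the test of abundant genes were chosen after the results had been seen. The changes from 0 h at different times differed from each other by the test of the difference itself in 2 contrasts. Those at 4 h and 1 h differed for 38 genes and those at 24 h and 4 h for 65 genes. Time in culture and handling are not separated from the change to air. Both counts rest on the labels of the 1 h and 24 h libraries.

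Among the 4 libraries labelled 1 h and 24 h, each correlated best with a library of the other label, and over all 8 libraries 1 h library 1 was closest to 0 h library 2 (r = 0.986, beside 0.985 with 24 h library 2), a crossing that an exchange between 1 h and 24 h alone does not address. A split of these 4 libraries that joined 1 h library 1 with 24 h library 2 and 1 h library 2 with 24 h library 1 called 1038 genes between its pairs, whereas the labelled split and the split by library number called 0 each (63 and 87 genes at an unadjusted p under 0.05 in limma). This split was taken from the correlations already seen and restates them, as a structure of the samples that the labels do not describe, and is no independent test of a cause. The deviations of same-numbered 1 h and 24 h libraries correlated at -0.73. This restates the crossing and would hold against an effect of the experiment that the number marks only if the labels are right. For the other pairs of groups the correlations were 0.01, 0.35, 0.09, 0.11 and 0.16, so such an effect stays open. Unequal depth is argued against. After thinning to the smallest library, the lower crossed correlation still exceeded the highest other one among these 4 libraries by 0.025. An exchange of labels between a 1 h and a 24 h library may account for the pattern and stays open, as does a difference between cultures that does not follow the library numbers, which was not tested.

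More genes fell than rose at 4 h. Unequal depth is argued against, since 81.9% of the calls fell after thinning, beside 82.2% before. The 93 most abundant genes, 1% of those tested, took 16.2% of the reads at 0 h and 20.4% at 4 h, which would lower the RPKM of the rest by a log2 of 0.07 (-0.07), part of the median shift of -0.20. For the 933 most abundant, 10% of the genes, the shares were 48.1% and 54% and the implied shift was -0.17. A larger share of reads in abundant genes may thus explain part of the surplus of falls and cannot be told apart from a fall of many low genes in air, which was not tested, because RPKM gives shares of reads and no absolute amounts.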

How the results depend on the processing

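Leaving out libraries 1 or 2 at both 1 h and 24 h, thinning of reads and a separate 0 h library for each time were chosen after seeing the data. The cause of the changes below was not tested. Some settings put fewer genes or libraries in the fit or added a fold threshold, which by itself alters how many genes can be called. With 1 library left in a group, that library was assumed to vary like the others and added nothing to the estimate of the spread. With 1 library left at both 1 h and 24 h, the spread came from the 0 h and 4 h pairs alone. At 4 h against 0 h (1131 genes), the count was 678 at a mean of at least 10 RPKM, 702 with trimmed-mean scaling, 614 with quantile normalization, 682 with an added 2-fold threshold, 697 with voom and 1883 with only the compared groups. With both libraries numbered 2 left out at 1 h and 24 h it was 1886, and with both numbered 1 left out 1887. Under these 2 settings in turn, the count at 1 h against 0 h was 0 and 210, at 24 h against 0 h 258 and 57, at 4 h against 1 h 129 and 395, at 24 h against 4 h 414 and 263, and for the F test 759 and 911. Genes called at both 4 h and 24 h then numbered 173 and 35, and with both numbered 1 left out 139 were called at both 1 h and 4 h and 17 at both 1 h and 24 h. With only the compared groups, 1 gene was called at 24 h against 0 h, and 0 at 4 h against 1 h and at 24 h against 4 h.

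At 4 h against 1 h (38 genes), the count was 79 with a pseudocount of 0.1, 19 without a filter, 68 with TPM and 23 with voom. At 24 h against 4 h (65 genes), it was 12 without a filter, 23 with quantile normalization, 22 without trend or robust moderation and 33 with voom. For the F test (170 genes), it was 99 at a mean of at least 10 RPKM, 79 with quantile normalization and 111 with voom.

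Leaving out each library in turn gave 0 to 1 genes at 1 h against 0 h, 40 to 1531 at 4 h against 0 h, 0 to 14 at 24 h against 0 h, 0 to 106 at 4 h against 1 h, 0 to 41 at 24 h against 4 h and 0 to 286 in the F test. The overlap of calls ranged from 0 to 1 for 1 h and 4 h, from 0 to 4 for 4 h and 24 h and from 0 to 1 for 1 h and 24 h. For the named genes, 0 of 264 alternative values changed direction and 97 were no longer called. Their direction was largely fixed by the naming rule. It asked for no overlap between the groups compared, so leaving out a library could not turn it. Some settings, such as the block, leave the fold change itself unaltered.

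With the replicate number as a block, 830 genes were called at 4 h against 0 h, 0 at 4 h against 1 h and at 24 h against 4 h, and 33 in the F test. Of the genes named at 4 h against 0 h, g4952, g4050 and g2865 lost their calls with the block (limma adjusted p = 0.0707, 0.0545 and 0.0516) and g897 kept its call (0.0464). The labels give the libraries a number and do not say whether it marks the experiment. Correlations of deviations between same-numbered libraries were 0.01, 0.35 and 0.09 for 0 h with 1 h, 4 h and 24 h. They were 0.11 for 1 h with 4 h, -0.73 for 1 h with 24 h and 0.16 for 4 h with 24 h.

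Gene list alternatives, and camera with an estimated correlation, were not run because no list was measured. The F test was not run with only the compared groups. The share of F-called genes that changed most at 4 h has no value without a 0 h or a 4 h library, since none was called. Depth sets how low a gene can be followed. In simulated data with equal spread in all groups, for 4 h against 0 h with 9305 genes, 4-fold changes were recovered at 93.9% and 2-fold changes at 39%.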

Other observations

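The tests of this part were all chosen after the fold changes at 4 h had been seen. Genes that rose at 4 h included runs of neighbours on the scaffolds. The longest run was on scaffold00514 from 2019054 to 2036037, a stretch of 16984 bp with 4 consecutive genes that rose, the first 3 on the minus strand and the last on the plus strand. Their log2 fold changes ran from 4.33 to 7.35. Their means lay between 4.36 and 163.45 RPKM at 0 h and between 246.2 and 3290.3 RPKM at 4 h. g4050, named for the comparison of 4 h with 0 h, is among them. Another 6 runs held 2 genes each. On scaffold00661, from 19537 to 33688, g4952 lay head to head with a gene whose log2 fold change was 3.64. On scaffold01012, from 2626639 to 2632747, a head-to-head pair had log2 fold changes between 1.49 and 2.06 and levels between 1003.8 and 6478.9 RPKM at 4 h. These runs were picked after their values had been seen.

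Of the 930 genes that fell, 96 adjacent pairs were counted against a mean of 74.0 in 10000 shuffles within bins of expression (one-sided permutation p = 0.0049, adjusted p = 0.014 over 17 such tests). The count lay above the 95% bound of the shuffles (88) and below their highest value (107). This argues against chance placement of these calls without excluding it. Setting the longest run aside was not tried for genes that fell, and calls made after scaling between libraries were not put to this test. Of the 201 that rose there were 9 adjacent pairs against 3.34 (permutation p = 0.0069, adjusted p = 0.015), but 3 of the 9 lay in the run on scaffold00514. With its 4 genes set aside 6 were left against 3.20 (permutation p = 0.099, adjusted p = 0.20 over 6 such tests), so chance stays open for genes that rose. Transcripts that run on into the next gene stay open for the pairs that rose. Same-strand pairs that rose numbered 3 against 1.20 (permutation p = 0.12, adjusted p = 0.16). Without that run 1 was left against 1.15 (permutation p = 0.69, adjusted p = 0.83), a count too small to exclude such transcripts. Head-to-head pairs, which point away from each other, numbered 5 against 1.04 (permutation p = 0.0034, adjusted p = 0.014). Without that run they numbered 4 against 0.99 (permutation p = 0.017, adjusted p = 0.10). Tandem copies that share reads also stay open: coding lengths within the pairs that rose differed by a median absolute log2 ratio of 1.45, beside 0.94 in other adjacent pairs, but single pairs spread from 0.26 to 1.97 without the extremes.

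Of the pairs that fell, 36 were head to head against 23.32 in shuffles (adjusted permutation p = 0.015), 33 on the same strand against 26.88 (adjusted permutation p = 0.16) and 27 tail to tail against 23.81 (adjusted permutation p = 0.31). Tail-to-tail pairs that rose numbered 1 against 1.10 (adjusted permutation p = 0.71). The difference between orientations itself was not tested. Among the 54 genes that rose 4-fold or more, 4 pairs were adjacent against 0.24 (adjusted permutation p = 0.0043), 2 of them on the same strand against 0.09 and 2 head to head against 0.07 (adjusted permutation p = 0.014 each). These 4 pairs came from 2 loci, 3 from the run on scaffold00514 and 1 from scaffold00661, and without the run 1 pair was left against 0.20 (adjusted permutation p = 0.27). With the 0 h and 4 h libraries alone in the fit, 28 pairs rose against 13.95 (adjusted permutation p = 0.0043) and 211 fell against 185.87 (adjusted permutation p = 0.03).

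Over all adjacent tested genes the relation was weak. Ranked log2 fold changes of neighbours correlated at 0.05 for 2335 head-to-head pairs, 0.04 for 2669 same-strand pairs and 0.02 for 2393 tail-to-tail pairs. The highest of 1000 shuffles was 0.07, 0.06 and 0.07, a bound that does not test whether a weak relation is present. With gaps up to 1000 bp and over 1000 bp in turn, same-strand pairs stood at 0.07 and 0.01. Head-to-head pairs stood at 0.05 in both, and tail-to-tail pairs at 0.01 and 0.03. The difference between the gaps was not tested. The log2 fold change at 4 h was also nearly unrelated to the structure of the gene models. Among 5 relations computed across 9326 genes, which are not independent replicates, Spearman's rho was 0.03 with the number of coding exons and 0.02 with coding length. It was 0.03 with gene span and 0.02 with the noncoding share of the span. The remaining relation was with mean RPKM, a level and no part of the model structure, and its rho was higher, at 0.15.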
